A study of Mus musculus with 2 samples.

How the data were processed

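Total RNA of small intestinal crypts from wild-type mice was made into libraries with an MGI kit and sequenced on an MGI instrument, per the labels' protocols. The kit's handling of ribosomal RNA and of strand, the read length, the aligner, the circRNA caller and its filters are not given in the sources used here. The genome build was mm10, per the submitters' processing notes. The deposited table gave for each circRNA its position, type, Ensembl identifier, gene name, raw counts of back-splice junction reads per library and a CPM value per library, per the file headers. The deposited counts were whole numbers that summed to 3546 in replicate 1 and 4441 in replicate 2. The deposited CPM values were a normalised signal, each count times a constant of its library (272 per read in replicate 1 and 233 in replicate 2), with column sums of 964714 and 1036580, so they were not scaled to the listed totals. TMM factors computed here from the listed counts with edgeR 4.0.16 (1.04 and 0.965) gave the same constants, 272 and 233. No column of linear reads and no comparison by the authors was used here, so the planned comparison of circular with linear levels and the planned description of comparison columns were not made.

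Libraries were grouped by the labels into 1 group of 2 samples, replicates 1 and 2. Columns were matched to samples by the sample titles in their names, and 0 columns of sample values were left unused. Levels were computed as CPM of the listed back-splice reads of each library, with mean and SD over n = 2. A library's total covers only the listed back-splice reads and is not its sequencing depth, which is not used here. The listed counts appear to have passed a minimum of 2 reads in a library, because of 373 circRNAs with 2 reads in total 1 had a read in each library, although 41 circRNAs with a single read are listed. No fold is therefore printed against a listed 0. Shares of reads and of circRNAs are given with 95% Clopper-Pearson intervals, which cover counting error only. With 1 read worth 282 or 225 CPM, a circRNA near the median of 3 reads carried a large counting error.

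Positions were compared with the GENCODE mouse annotation release M21, which is on the same build. Of 885 Ensembl identifiers, 884 were found in it. A circRNA was called at splice sites of 1 transcript when its start was the start of an exon other than the leftmost and its end was the end of an exon other than the rightmost of the same transcript. Where several transcripts matched, protein-coding genes and transcripts, the basic set and the longest coding sequence were preferred, and exon numbers, spliced length and flanking introns were taken from that transcript. The host was the gene of that transcript, and otherwise the named gene with most matching ends. The 90 circRNAs with more than 1 named gene were assigned in this way, and 4 had no gene. Reads shared between near-identical copies, such as butyrophilin-like genes and ribosomal RNA genes, and reads of antisense partners could not be separated from the table. Genome sequence was not used here.

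The main tests were fixed before the data were examined. Agreement between libraries used Pearson r and Spearman rho of log2(CPM + 1) with 100000 permutations, a chi-square test over circRNAs with at least 5 expected reads in each library, and binomial sampling as the expectation for listing in 1 library. The setting of single reads to 0 and the bands of 5 to 9 and at least 10 reads were chosen after the counts were seen, as were the exact binomial test of each circRNA's reads and of each list's reads against the library totals (Benjamini-Hochberg adjustment, threshold 0.05) and the simulated correlations. Gene lists covered 9 sets of cell type markers (intestinal stem, proliferating, Paneth, goblet, enteroendocrine, tuft, absorptive enterocyte, immune, and stroma, muscle, endothelium and glia), 5 signalling pathways (Wnt, Notch, BMP and TGF-beta, Hippo, and EGF receptor, MAPK and PI3K), chromatin regulators, RNA-binding and splicing regulators, and often reported circRNA hosts. Presence was tested with Fisher's exact test against 20620 multi-exon protein-coding genes, of which 813 (3.94%) were hosts, and against 10000 random lists matched on gene length deciles. Level was tested as the percentile of a list's median among 10000 random lists of hosts, for lists with at least 3 hosts. Cdr1os and Mll5 were not found in the annotation under those symbols, and lists were counted on the multi-exon protein-coding members. Pvt1, a noncoding host among the often reported genes, entered levels and shares but not presence.

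Genes named are the 25 circRNAs with the highest mean level, the 5 hosts with most circRNAs, the 5 circRNAs with the largest log2 ratio between libraries among those above the median level, and up to 3 genes per list with the highest mean level, ties being broken alphabetically. Some genes that this rule selects are not reported here. Any other gene named was chosen after its values were seen. Those 5 by ratio were both Rpph1 features, CT010467.1, Gigyf2 and Cyp4f14. Each was listed at 0 in 1 library, so its ratio of CPM + 1 was set by the pseudocount and served for this choice only. Alternatives covered scaling (none, TMM, median-ratio factors), a minimum mean of 5 reads, a pseudocount of 0.1 or no log, detection from 2 reads, the lower library, circRNAs in both libraries, each library alone, sums or maxima per gene, exon edges within 2 bases and other backgrounds. Restriction to circRNAs at splice sites of 1 transcript, its combination with length matching, the correlation over circRNAs in both libraries and list shares without Pan3 were added after the data were seen.

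The binomial test and the list percentile were tested on simulated data. With library 2 changed against library 1 for 180 circRNAs of at least 10 reads, out of 1132, the test recovered 12.8% of 2-fold, 80.6% of 4-fold and 100% of 8-fold changes. For 200 circRNAs of any read number it recovered 0%, 14.0% and 64.0%, and at most 3 unchanged circRNAs were called. The simulated counts had counting error only and no minimum of 2 reads, and the library share was taken from the unchanged circRNAs. The measured libraries varied by more than counting error, so these rates of recovery and of false calls do not carry over to them. For random lists of 12 among 823 hosts, 5% of unchanged and 97.5% of 4-fold raised lists were called at an unadjusted p under 0.05. Smaller lists and adjusted p-values were not simulated, so this rate does not carry over to them. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.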

Results

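Circular RNAs (circRNAs) were profiled by RNA sequencing in small intestinal crypts of wild-type mice. CircRNAs are closed loops that form when the end of an exon is joined back to the start of the same or an earlier exon, and a read across that join is a back-splice read. Crypts are the epithelial pockets that hold the stem cells, their dividing progeny and Paneth cells. The sample titles name crypts, whereas the cell type entry names stem cells, and no sort is recorded. The group held 2 libraries (replicates 1 and 2) and the series had no other group, so the design implied a description of the circRNAs with high levels and a comparison of the 2 libraries. The table listed 1132 circRNAs, with 3546 back-splice reads in replicate 1 and 4441 in replicate 2. Levels are given as CPM, here each circRNA's back-splice reads scaled to the total of the back-splice reads listed for the library, so that 1 read was worth 282 CPM in replicate 1 and 225 CPM in replicate 2. Means are given ± SD over both libraries (n = 2). The labels do not say that the libraries came from separate animals, so the SD, and any difference between the libraries, measures a spread that may be technical. The p-values for differences between the libraries are set against counting error, and those for gene lists, chromosomes and structure run across genes or circRNAs.

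The question stated for the series was which circRNAs were highly expressed. The highest mean level belonged to a circRNA of Ogdh (ENSMUSG00000020456), the gene for the first enzyme of the 2-oxoglutarate dehydrogenase complex, at 19524 ± 93.1 CPM. A circRNA of Rasa2, which encodes a GTPase-activating protein of RAS, followed at 18820.4 ± 503.6 CPM, and another circRNA of Rasa2 reached 14537 ± 1415 CPM. CircRNAs of Sis, the gene of the brush-border disaccharidase sucrase-isomaltase, and of Btnl1, a butyrophilin-like gene of the intestinal epithelium, reached 16680.2 ± 1935 and 16509.7 ± 216.7 CPM. Slc43a2, an amino acid transporter gene, gave 15867 ± 7472 CPM, and its reads differed between the libraries (75 and 47 reads, exact binomial test, two-sided, Benjamini-Hochberg adjusted p = 0.0147 over 1132 circRNAs).

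The Ogdh circRNA spanned chromosome 11, 6313788 to 6317080 (mm10), exons 3 to 4 of 23, with a spliced length of 295 bases. On chromosome 9 both Rasa2 circRNAs ended at 96611499, the outer edge of exon 2, and they started at 96602713 (exons 2 to 4 of 24) and at 96591950 (exons 2 to 5). The Sis circRNA lay at chromosome 3, 72958113 to 72960367 (exons 5 to 6 of 48), that of Btnl1 at chromosome 17, 34380961 to 34382488 (exons 4 to 8 of 10), and that of Slc43a2 at chromosome 11, 75543158 to 75545830 (exons 3 to 5 of 14). Med13l, which encodes a Mediator subunit, gave a circRNA of exon 2 alone (chromosome 5, 118593333 to 118593570, 238 bases) at 13862 ± 1134 CPM. Fam160b1 (chromosome 19, 57378549 to 57379175, exons 6 to 7) reached 12652 ± 3245 CPM, and Vapa, which encodes a membrane contact protein of the endoplasmic reticulum, reached 11748 ± 263 CPM (chromosome 17, 65592291 to 65595054, exons 2 to 4). The circRNA of Erbin, a scaffold protein gene, covered exons 2 to 4 at chromosome 13, 103884143 to 103889285, and was the only circRNA among the top 25 with the annotated start codon inside. Its level was 8904 ± 1765 CPM.

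Mettl9 and Cds1 were next in rank. Cds1, which encodes a CDP-diacylglycerol synthase, had a circRNA of exons 2 to 5 at 8142 ± 50.9 CPM and a circRNA of exons 3 to 5 at 6200 ± 2399 CPM. Mettl9, a histidine methyltransferase gene, had 8422 ± 2738 CPM, Alg12, a mannosyltransferase gene of N-glycan assembly, had 6845 ± 2102 CPM, and Fryl had 6704 ± 2302 CPM. Cnot6l, a deadenylase gene, and Ptbp3, a polypyrimidine tract binding protein gene, had 7521 ± 1464 and 6114 ± 270.6 CPM. Enpep, which encodes the brush-border glutamyl aminopeptidase, and Eed, which encodes a Polycomb subunit, had 5186 ± 2238 and 5183 ± 949 CPM. Esyt2, the amino acid transporter gene Slc7a8, Lrch3 and Esco1 closed the top 25 at 5129 ± 1521, 5128 ± 72.7, 5128 ± 72.7 and 5100.2 ± 1162 CPM.

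Among these 25 circRNAs, 23 had both ends at annotated splice sites of 1 transcript, and the reads of those 23 lay within 2-fold of each other in CPM. The other 2 were features within short noncoding genes. Rpph1, the gene of the RNase P RNA, had 90 reads in replicate 1 and was listed at 0 in replicate 2 (chromosome 14, 50807500 to 50807696). CT010467.1, annotated as a ribosomal RNA gene, was listed at 0 in replicate 1 and had 101 reads in replicate 2 (chromosome 17, 39848501 to 39848715). CircRNAs that started at exon 2 made up 13 of the 25.

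**Figure D1:**
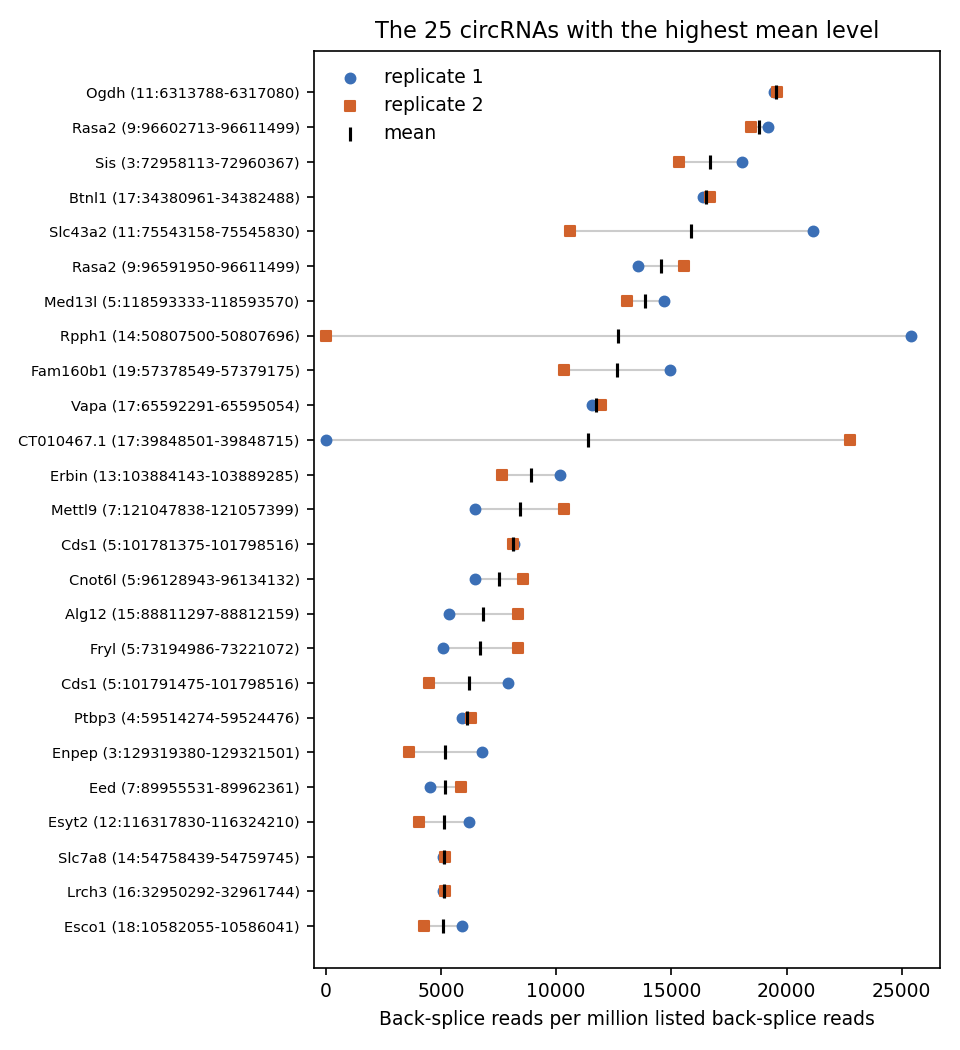
Level of the 25 circRNAs with the highest mean, in CPM of the listed back-splice reads of the library, with mm10 positions; circles are replicate 1, squares replicate 2 and bars their mean. Ogdh stands highest at 19524 CPM, and Rpph1 and CT010467.1 are each listed at 0 in 1 library.

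**Figure D2:**
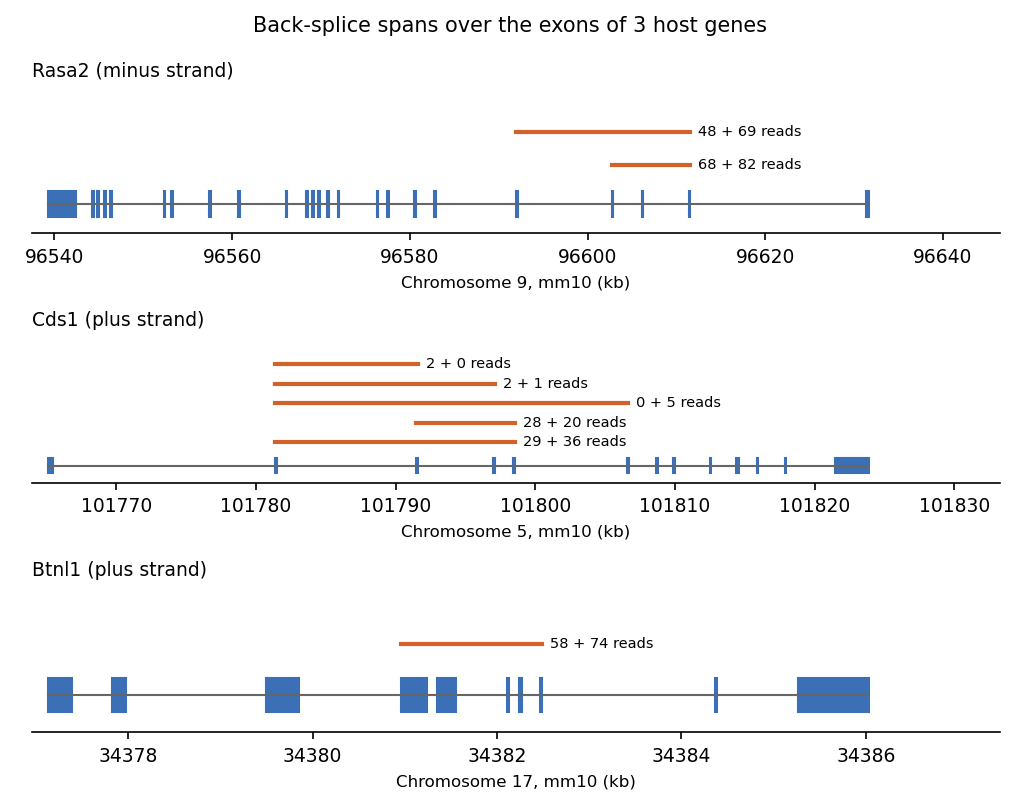
Back-splice spans (orange) of circRNAs at splice sites over the annotated exons (blue) of Rasa2, Cds1 and Btnl1, in kilobases of mm10, with the reads of replicate 1 and replicate 2 added beside each span. The Rasa2 spans share the edge of exon 2 at 96611499 on chromosome 9.

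A small set of circRNAs, led by Ogdh, Rasa2 and Sis, held much of the signal. The top 10 took 17.4% of the reads in replicate 1 (95% Clopper-Pearson interval 16.2 to 18.7%) and 13.2% in replicate 2 (12.2 to 14.2%), a mean of 15.3 ± 3.02%. Rpph1, which was not at splice sites, was in the top 10 with 2.54% of the reads in replicate 1 and 0% in replicate 2, and it widened this gap. The top 50 took 35.2 ± 1.38% and the top 100 took 47.3 ± 1.69%. Such intervals cover counting error only, because reads without molecular identifiers are not independent molecules.

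Foxp1, a forkhead transcription factor gene, hosted the most circRNAs (8), followed by Cds1 (6) and by Arhgap26, B4galnt2 and Fut8 (5 each). Of the 8 listed for Foxp1, 2 were at splice sites of 1 transcript, and the leading feature (chromosome 6, 99435216 to 99456580) was listed as intronic, with 0 and 16 reads. Cds1 used 2 circRNAs above all, and its leading circRNA held 52.0% of its reads. B4galnt2 and Fut8, which encode glycosyltransferases, had no circRNA with reads in both libraries, and Arhgap26 had 1. In all, 823 host genes were counted, of which 201 (24.4%) had at least 2 circRNAs. With circRNAs seen in both libraries alone, 44 hosts had at least 2. The leading circRNA held a median of 65.9% of a host's reads among the 201, and 261 of the 1008 circRNAs at splice sites (25.9%) shared 1 end with another circRNA of the same host.

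The comparison of the 2 libraries asked how far levels repeated. Slc43a2, Atp9a and Bub1b were the circRNAs present in both libraries whose reads differed: Slc43a2 had 75 and 47 reads, Atp9a, a phospholipid flippase gene, 16 and 2, and Bub1b, a gene of the spindle checkpoint, 4 and 31 (adjusted p = 0.0147, 0.0136 and 0.00664, exact binomial test, two-sided). Of 1132 circRNAs, 18 passed this test, 13 higher in replicate 1 and 5 higher in replicate 2, and 106 had an unadjusted p under 0.05. The 18 included 15 listed in 1 library, such as Cyp4f14, a cytochrome gene (17 and 0 reads, chromosome 17, 32907647 to 32908036), Gigyf2 (0 and 22 reads, chromosome 1, 87364104 to 87380008), Vwa8 and Synpo (14 and 0 each) and Ube3a, a ubiquitin ligase gene (0 and 15). Rpph1 appeared again with an antisense feature of 31 and 0 reads (chromosome 14, 50807447 to 50807694). Among the 18, 9 were at splice sites of 1 transcript. The test takes a listed 0 as 0, although it may hide a single read, so of the 15 calls those nearest the threshold are the least certain. Atp9a, Vwa8, Synpo and Ube3a were outside the naming rule and were chosen after their values were seen.

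Replicate 1 listed 695 circRNAs and replicate 2 listed 767, and 330 were in both. The other 802 (70.8%) were in 1 library, 365 in replicate 1 and 437 in replicate 2. Shared circRNAs, among them 23 of the top 25, held 68.6% of the reads of replicate 1 and 66.4% of those of replicate 2. Across all 1132 circRNAs the log2(CPM + 1) values had a Pearson r of -0.375 (permutation p = 1e-05, the smallest that 100000 permutations give) and a Spearman rho of 0.045 (permutation p = 0.129). No circRNA is listed at 0 in both libraries and 802 are at 0 in 1, so 0 is not the value of r for libraries of equal content. Splitting each circRNA's reads by the library totals, with single reads set to 0, gave an r of -0.172 (95% of 1000 simulations from -0.193 to -0.150) and a rho of 0.366 (0.334 to 0.401). Both were above the observed values, but circRNAs left at 0 in both libraries were dropped from the simulations. That removed circRNAs with a single read and those with 1 read drawn for each library, which the observed values include. The gap may come partly from this setting, so its size does not measure a difference between the libraries. Over the 330 shared circRNAs, a set chosen after seeing the data, r was 0.747 and rho 0.658 (each permutation p = 1e-05), and without the log r over all circRNAs was 0.701. These correlations run across circRNAs, which are not independent replicates. Of the 167 shared circRNAs with at least 10 reads in total, 130 (77.8%) lay within 2-fold, and the SD of the log2 ratio was 0.90 against 0.75 from counting alone. Set against counting noise alone, the libraries had a chi-square of 588 on 142 degrees of freedom (143 circRNAs, p = 1.57e-55), 304 on 131 for circRNAs at splice sites (p = 8.48e-16) and 230 on 131 for shared circRNAs (p = 2.27e-07). Reads without molecular identifiers are not independent, so these p-values are too small.

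**Figure D3:**
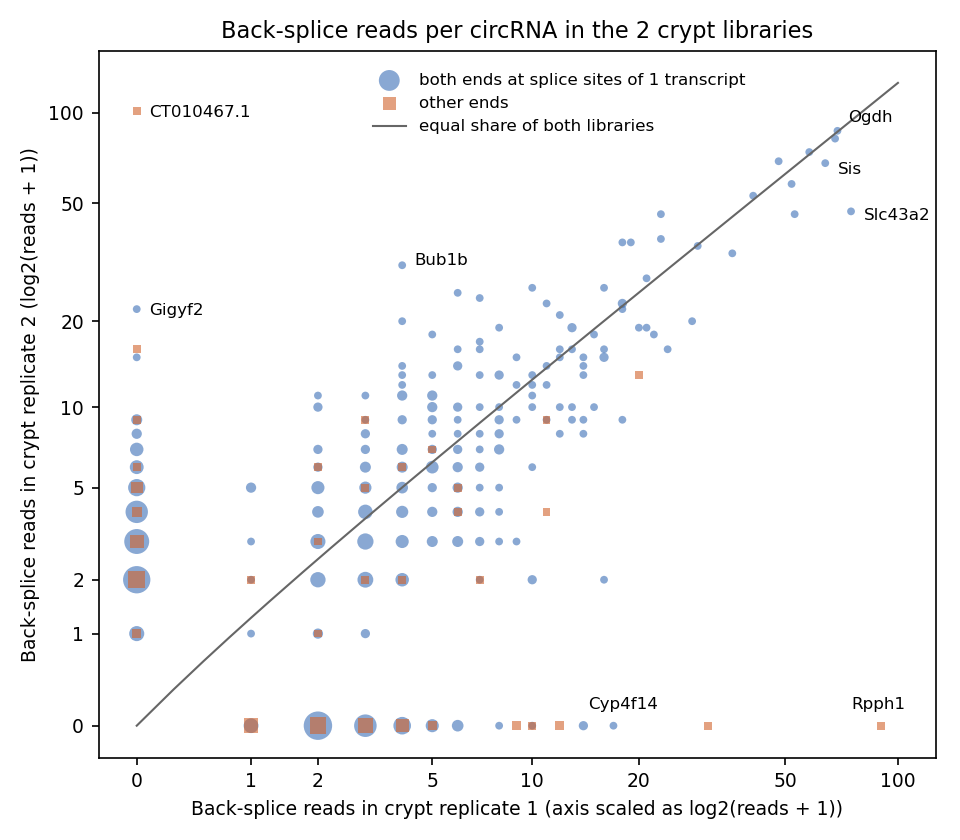
Back-splice reads of each circRNA in replicate 1 (x axis) and replicate 2 (y axis), both on a log2(reads + 1) scale, with marker area growing with the number of circRNAs at that pair of counts; circles have both ends at splice sites of 1 transcript and squares do not. Ogdh, with 69 and 87 reads, lies on the line of equal shares, and Rpph1 (90 and 0) and CT010467.1 (0 and 101) lie on the axes.

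Listing in 1 library was frequent at low counts and also reached abundant circRNAs such as Gigyf2 and Cyp4f14. Of 180 circRNAs with at least 10 reads in total, 13 were in 1 library, where binomial sampling with single reads set to 0 gave 1.14 and an upper limit of 4 (the upper end of the central 95% of simulated values). Among 213 circRNAs with 5 to 9 reads, 75 were in 1 library against 49.2 from sampling (upper limit 61). A listed 0 may hide a single read, since 372 of the 373 circRNAs with 2 reads in total had both reads in 1 library and 1 had a read in each.

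Most circRNAs were exonic and matched annotated splice sites. The authors' deposited type was exon for 1054 circRNAs (93.1%), intron for 53, antisense for 21 and intergenic for 4. Both ends lay exactly at exon edges of a named gene for 1020 circRNAs (90.1%, interval 88.2 to 91.8%), and both ends were splice sites of 1 transcript for 1008 (89.0%). A further 69 had 1 end at a splice site, 44 had none and 11 had ends in different transcripts. Foxp1, Etv6 and Mgam had features with 1 end at a splice site, and Rpph1, CT010467.1, Alpi, Crip1 and Ada had features with none. Over the 1008, the median spliced length was 368 bases (quartiles 290 and 501), 794 (78.8%) held 2 to 4 exons, 353 (35.0%) started at exon 2, and 154 of 998 (15.4%) held the annotated start codon, as Erbin did. The introns on either side had medians of 9232 and 9284 bases, and those of the Med13l circRNA measured 32475 and 77442 bases.

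Level was weakly related to structure. CircRNAs with longer flanking introns had higher levels (Spearman rho = 0.0995, permutation p = 0.00157, Benjamini-Hochberg adjusted p = 0.00628 over 4 relations, Pearson r = 0.0914, adjusted p = 0.0119, 1008 circRNAs). The adjusted p of this rho ranged from 0.0233 without replicate 2 to 0.378 among circRNAs in both libraries (rho = 0.0499), and was 0.0742 without replicate 1 (rho = 0.074). Exon number (rho = -0.0681), spliced length (rho = -0.0571) and genomic span (rho = -0.0519) had adjusted p of 0.0619, 0.0811 and 0.0811 (0.0243, 0.117 and 0.0456 without replicate 2), while their Pearson r of -0.0872, -0.0675 and -0.0597 had adjusted p of 0.0119, 0.0441 and 0.0443.

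Host genes were then set against fixed gene lists. Among the cell type markers, the absorptive enterocyte list had the most hosts, 10 of 28 genes (35.7%, interval 18.6 to 55.9%) against 3.90% of the other multi-exon protein-coding genes (Fisher's exact test, two-sided, adjusted p = 2.51e-07 over 17 lists). Sis led with 16680.2 ± 1935 CPM, then Enpep with 5186 ± 2238 CPM and Mgam, the maltase-glucoamylase gene, with 3410.4 ± 1957 CPM. Against genes of matched length, 1.33 hosts were expected (adjusted p = 0.00113, from the smallest p that 10000 random lists give). Sis, Enpep, the glucose transporter gene Slc5a1 and Cubn were the 4 hosts with a circRNA at splice sites of 1 transcript, and these 4 gave an adjusted p of 0.0458 in Fisher's exact test and, against 1.24 of matched length, of 0.211. With circRNAs found in both libraries there were 5 enterocyte hosts (adjusted p = 0.000137, Fisher's exact test). Mgam, Alpi, Npc1l1, Apob, Apoa1 and Apoa4 had other features. Those of Npc1l1, Apob and Apoa1 were listed as antisense with no end at a splice site, and the 10 hosts include them.

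The goblet cell list had 3 hosts of 12 genes (25%, adjusted p = 0.025, Fisher's exact test), Zg16, Fcgbp and Muc2, with 5, 3 and 1 reads in replicate 1 and none listed in replicate 2. None of the 3 had a circRNA at splice sites of 1 transcript, and the features of Fcgbp and Muc2 were listed as antisense. The immune list had 3 of 21, with Adgre1, a macrophage marker gene, at 2591 ± 2068 CPM and the lymphocyte factor genes Bcl11b and Ikzf1 at 0 and 4 reads each (adjusted p = 0.0904). Bub1b, at 5124 ± 4854 CPM, was the single host of 26 genes of proliferating cells (adjusted p = 1). The stem cell list had 0 hosts of 25 genes, the Paneth list 0 of 9, the enteroendocrine list 0 of 18, the tuft list 0 of 14 and the list of stroma, muscle, endothelium and glia 0 of 26 (adjusted p = 0.817, 1, 1, 1 and 0.817). With 0.986 stem cell hosts expected, a lower rate was not detectable at this depth.

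Genes of growth factor signalling, chromatin and RNA binding hosted circRNAs more often than other genes. The list of EGF receptor, MAPK and PI3K signalling had 12 hosts of 29 (41.4%, adjusted p = 3.1e-09), with Rasa2 at 33357 ± 911 CPM over its circRNAs, the lipid kinase gene Pik3c2a at 4311 ± 683 CPM and Map2k1 at 3663 ± 403 CPM. Chromatin regulators had 17 of 59 (28.8%, adjusted p = 1.14e-09), with Eed first, then the acetyltransferase gene Ep300 at 2029 ± 322 CPM and the methyltransferase gene Ehmt1 at 1972 ± 396 CPM. RNA-binding and splicing regulators had 11 of 40 (27.5%, adjusted p = 9.22e-07), with Ptbp3 at 8141 ± 1543 CPM and Cnot6l at 7521 ± 1464 CPM. The list of often reported circRNA hosts had 13 of 37 (35.1%, adjusted p = 4.25e-09), with Pan3 at 3661 ± 2784 CPM, Rere at 2986 ± 235 CPM and Nfix at 1437 ± 759 CPM. These 4 lists passed against genes of matched length as well, with 2.67, 6.19, 3.22 and 4.04 hosts expected (adjusted p = 0.00113, 0.00113, 0.00204 and 0.0017). Expression was not matched, so the tests do not separate the kind of gene from its expression. Pan3 and Mbnl1 are hosts in both the RNA-binding and the often reported lists.

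Hosts in the developmental pathways were fewer in number, a contrast with the lists above that was not tested. Wnt signalling had 5 of 38 (adjusted p = 0.0342), with the co-receptor gene Lrp6 at 1972 ± 396 CPM, Tnks2 at 1437 ± 759 CPM and Fbxw11 at 0 and 6 reads. Hippo signalling had 5 of 25 (adjusted p = 0.00734), with Patj at 2029 ± 322 CPM and Nf2 and Taok1 at 0 and 3 reads each. Both calls were lost against genes of matched length (adjusted p = 0.738 and 0.302). BMP and TGF-beta signalling had 2 of 26, the receptor gene Acvr2a at 2902 ± 283 CPM and Smad1 at 1099 ± 357 CPM, and Notch signalling had 2 of 27, Itch at 761 ± 121 CPM and Numb at 2 and 0 reads (each adjusted p = 0.446). Hosts had a median length of 77.3 kb against 18.3 kb for other genes, and expression of the linear host RNA was not part of the test.

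**Figure D4:**
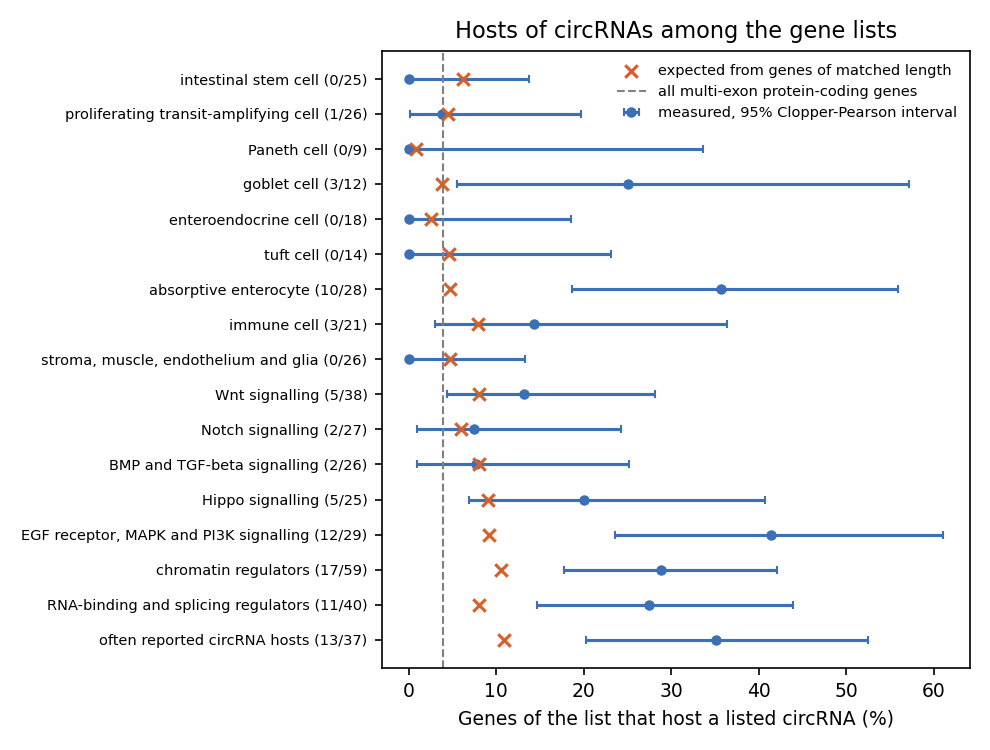
Percentage of the genes of each list that host a listed circRNA (circles, 95% Clopper-Pearson intervals), with the percentage expected from genes of matched length (crosses) and the rate of all multi-exon protein-coding genes (dashed line, 3.94%). The enterocyte list stands at 35.7% and the stem cell list at 0.

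Summed per gene, levels of the listed hosts did not stand apart. Of 9 lists with at least 3 hosts, none passed, with or without adjustment, against 10000 random lists drawn from the 823 hosts. RNA-binding and splicing regulators came closest, with a median of 1296 CPM against 507 CPM for other hosts (permutation p = 0.0514 over random lists, adjusted p = 0.463), and the enterocyte list had a median of 775 CPM (79.7th percentile of random lists, adjusted p = 0.984). The adjusted p of the other 7 lists was 0.984 for each.

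The share of reads held by a list passed a test against counting error for 6 of 12 lists (exact binomial test, two-sided, adjusted over 12 lists). Because the libraries vary by more than counting error, these p-values are too small, and the calls near the threshold are the least certain. Enterocyte hosts held 3.69% of the reads in replicate 1 and 2.34% in replicate 2 (adjusted p = 0.00201), and goblet hosts held 0.254% and 0% (adjusted p = 0.00201). Bub1b, the proliferation host, held 0.169% and 0.856% (adjusted p = 0.000274), immune hosts 0.113% and 0.585% (adjusted p = 0.00201), often reported hosts 1.13% and 1.85% (adjusted p = 0.0253), and RNA-binding regulators 2.59% and 3.49% (adjusted p = 0.0498). Pan3, with 6 and 25 reads, is in both of the last lists, and without it, an alternative also chosen after seeing the data, neither passed (0.959% and 1.28%, 2.43% and 2.93%, each adjusted p = 0.411). Restricted to circRNAs at splice sites, an alternative chosen after seeing the data, Bub1b and the immune hosts passed (adjusted p = 0.000491 and 0.0404), whereas enterocyte hosts held 2.98% and 2.16% (adjusted p = 0.0844), often reported hosts had an adjusted p of 0.0844 and RNA-binding regulators of 0.134. This test compares these libraries and not conditions.

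Host genes were unevenly spread over the chromosomes. Chromosome 12 held 47 hosts, among them Esyt2 and Fut8, where 23.6 were expected from its 598 genes (Fisher's exact test, two-sided, adjusted p = 0.000179 over 21 chromosomes). Chromosome 7, with Mettl9 and Eed, held 50 against 73.2 (adjusted p = 0.0338), and chromosome Y held 0 of 153 genes against 6.03 (adjusted p = 0.0354). With exons as the background, chromosome 12 alone passed (adjusted p = 0.00259). Neither gene length nor expression of the linear RNA was part of these tests, so a cause of the uneven spread was not tested. The sex of the mice was not used here, and without it the 0 of chromosome Y cannot be read as uneven spread.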

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

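The restriction to circRNAs at splice sites of 1 transcript, alone or with length matching, the correlation over circRNAs in both libraries and list shares without Pan3 were chosen after seeing the data. Among alternatives to results that answer a comparison, 151 kept direction and side of the threshold or stayed within the spread, 15 lost a call, 5 gained one, 5 changed direction and 6 moved. Some of the 151 could not change, such as rho under another pseudocount or scaling and the lists without any host. All 100 alternatives for the levels of the top 25 stayed within 1 SD, which for single libraries holds by construction with n = 2, and 17 of the 25 stayed in the top 25 under every ranking tried. The Pearson r between libraries, -0.375, was -0.0698 with a mean of at least 5 reads, 0.701 without the log and 0.747 in both libraries; rho, 0.045, was 0.312 with that minimum, 0.658 in both libraries and 0.102 at splice sites. CircRNAs that differed between libraries fell from 18 to 9 at splice sites. Hosts with at least 2 circRNAs fell from 201 to 44 in both libraries. Summed per host gene the top 50 held 39.8% and the top 100 54.0%, and at splice sites the top 100 held 49.3%. For flanking introns rho was 0.0499 in both libraries and 0.0740 to 0.0869 with either library alone, for span -0.0631 to 0.00671 and for exon number -0.0786 to -0.0368, where the last 2 passed without replicate 2.

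Hosts over expected for the goblet list, 6.34, were 0 in both libraries, at splice sites and at splice sites with length matching. These count as changes of direction, although only 0.161 hosts were expected with circRNAs in both libraries and 0.445 at splice sites. For Wnt, 3.34 became 3.92 in both libraries, 1.65 with length matching and 1.73 with splice sites added; for Hippo, 5.07 became 2.98, 2.21 and 2.32, and for enterocytes, 9.06 became 3.22 with both restrictions. The change in read share from replicate 1 to replicate 2 at splice sites was 0.835 points for RNA-binding regulators, -0.816 for enterocyte and 0.692 for often reported hosts, and without Pan3, which is in both of these lists of regulators and hosts, 0.502 for RNA-binding regulators and 0.325 for often reported hosts, each no longer passing. Chromosomes passing fell from 3 to 1 with exons as background. Fewer circRNAs or hosts enter the restricted tests, and beyond that the cause was not tested. The planned comparison of circular with linear levels was not run. Low read counts limit all of this, as the median had 3 reads. In addition 70.8% of circRNAs were in 1 library, which sampling of low counts did not account for in full.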

Other observations

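Except for the length-matched test of all 10 enterocyte hosts and Fisher's exact test of the stem cell list, the tests in this part were chosen after the result was seen. Solute carrier genes, which encode membrane transporters, supplied Slc43a2 and Slc7a8 among the top 25 and also Slc12a8, with 5 circRNAs and 3860 ± 274 CPM, Slc10a7 with 1099 ± 357 CPM and Slc44a1 with 761 ± 121 CPM (n = 2). In total 19 of 368 solute carrier genes were hosts (5.16%) against 3.92% of other genes. The test did not decide whether they host circRNAs more often, because the odds ratio was above 1 without passing (1.33, Fisher's exact test, two-sided, adjusted p = 0.222 over 2 families). Genes named Zfp, for zinc finger proteins, had 10 hosts of 392 (adjusted p = 0.222).

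Some features joined neighbouring members of a gene family. Slc28a2 and Gm14085 were joined over chromosome 2, 122452484 to 122518040, with 12 and 0 reads, and the major histocompatibility genes H2-D1 and H2-Q1 and the chloride channel accessory genes Clca4b and Clca4a were joined by 1 and 0 reads each. The leading antisense features of Ada, Crip1 and Pigr had 9, 9 and 4 reads in replicate 1 and 0 in replicate 2. All antisense features together held 106 reads in replicate 1 and 20 in replicate 2, and some were listed in replicate 2 only, such as that of Slc39a4 (0 and 2 reads). The antisense feature of Ppp2r3d, with 20 and 13 reads, was the 1 antisense feature found in both libraries.

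CircRNA placement within the host was not random. Of 747 hosts whose leading circRNA could be placed elsewhere in its transcript, 265 started at exon 2, where random placement of the same number of exons gave 96.5 (upper limit 114, permutation p = 0.0002 over 10000 random placements, the smallest they can give). Rasa2, Med13l, Vapa and Erbin were among them. Introns before exon 2 are often long, so flanking introns were compared over 474 of the hosts that started later, as in Ogdh and Slc43a2. Their geometric mean was 5102 bases against 1936 at random places (upper limit 2087, permutation p = 0.0002). Long flanking introns may therefore go with circRNA formation apart from exon 2, as a hypothesis from the same data, and Sis, with introns of 1814 and 645 bases, lies outside it.

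CircRNAs whose ends were not splice sites of 1 transcript, such as those of Rpph1, CT010467.1 and Alpi, were mostly in 1 library. Low counts alone are argued against, since at 10 or more reads 8 of 15 were in both libraries against 159 of 165 at splice sites (Fisher's exact p = 7.96e-06). Reads that do not come from back-splicing, for example template switching or misplaced linear reads, cannot be told apart from other causes, because the lower share at 5 to 9 reads (6 of 17 against 132 of 196, exact stratified p = 3.81e-06 over both read ranges) restates the pattern. An abundant linear RNA may supply such reads: enterocyte or goblet marker genes hosted 13 of these 124 features (9 genes) against 4 of 1008 at splice sites (Fisher's exact p = 2.95e-10), though linear levels were not used here. The features of these marker genes were known before this test, and several of 1 gene, such as the 4 of Mgam, were counted separately. Its p-value therefore restates what had been seen and decides nothing about linear RNA. No biological explanation was tested, and unannotated transcripts remain open.

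Enterocyte genes hosted listed circRNAs more often than other genes, though for Npc1l1, Apob and Apoa1 these were antisense features alone. Stem cell genes had none, where 0 of 25 lay within chance (Fisher's exact p = 0.624, unadjusted). Gene length is argued against as the whole cause over the 10 hosts (permutation p = 0.000200 with genes drawn within length deciles, the smallest that 10000 random lists give), but for the 4 hosts at splice sites the permutation p was 0.0622 (4 against 1.24), which leaves it open because the hosts are few. Villus cells carried into the preparations, for which no sort is recorded, could supply Sis (64 and 68 reads), Enpep (24 and 16), Mgam (17 and 9) and Alpi (11 and 4). In CPM all 4 of 4 such hosts with at least 10 reads had the larger value in replicate 1 (exact binomial p = 0.381, 0.0557, 0.0463 and 0.0348, unadjusted), and the read shares were 3.69% and 2.34% for enterocyte hosts, 0.254% and 0% for goblet hosts, 0.169% and 0.856% for Bub1b and 0.113% and 0.585% for immune hosts. These values set 1 library against 1 other with counting error alone, which decides nothing about cell content, so villus cells cannot be told apart from enterocyte genes read within crypts without linear values or a villus sample, and no biological explanation was tested.

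Most circRNAs were listed in 1 library. A minimum of 2 reads and sampling do not account for all of it, because 13 circRNAs with at least 10 reads were in 1 library where the upper limit was 4. The excess was in both classes, 6 of 165 at splice sites (upper limit 3), Gigyf2, Cyp4f14, Ube3a, Vwa8, Synpo and Abhd2, and 7 of 15 with other ends (upper limit 1). A difference in cell content, in amplification or in the caller's filters between the libraries may add to it, and these could not be separated with 2 libraries of 1 group.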
